A study of Homo sapiens with 2 samples.

How the data were processed

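RNA was measured in SKOV3 cells in 2 libraries, 1 of untreated control cells and 1 of cells given 15 µM thioridazine for 24 h. Groups were taken from the treatment field of the labels, since the treatment protocol text is identical for both samples. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was depleted and libraries were made with a directional kit, which keeps the strand of the RNA. The submitters' processing notes name FastQC, HISAT2, HTSeq 0.11.2, DESeq2 and limma 3.40.6 and the genome build GRCh38, with no role or order. The strand setting of the counting, the annotation release and any filter are not given in the sources used here.

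The authors deposited, for each library, a table with a count and an FPKM value (the count scaled to gene length and library total) per gene. The deposited count columns hold whole numbers, which sum to 11641110 in the control and 9364269 in the thioridazine library. The deposited FPKM values equal the count divided by a gene length and by the total of the same table's counts, so the rows listed account for the whole denominator. The 24226 rows are the same in both tables, and each has at least 1 count in the 2 libraries together. All 24226 identifiers and names match GENCODE 29. The length behind the FPKM equals the GENCODE 29 union exon length, within 0.5 bases, for 99.7% of genes, and coordinates are from that annotation. Counts above 0 were present for 21790 genes in the control and 21930 in the thioridazine library. Protein-coding genes took 97.8% and 96.8% of counts. For a gene of 1000 bases, 1 count is worth 0.0859 FPKM in the control and 0.107 FPKM in the thioridazine library, and a count of 0 allows up to 0.258 and 0.320 FPKM.

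The main measure was log2((thioridazine FPKM + 1)/(control FPKM + 1)), which understates the change of low genes. Genes with a mean of at least 1 FPKM over both libraries counted as expressed, and a gene was counted as higher or lower at a log2 ratio of at least 1 in size, a 2-fold limit on that scale. Plain folds are ratios of FPKM without a pseudocount, with 95% Clopper-Pearson intervals from the counts. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. With 1 library per group no test between conditions was possible, and no p-value, SD or count model was used. A gene at 0 counts in 1 library is given by the lower limit of its counting interval and by its ratio against 3 counts in that library, which takes the other count as exact.

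Before the data were examined, 34 gene lists were fixed, with the limits above and the rule for named genes. The lists are those given with their results, namely pyroptosis, autophagy machinery and receptors, lysosome, cholesterol synthesis, other SREBP, LXR, ATF4, NRF2 and YAP targets, ER chaperones, heat shock, metallothioneins, ferroptosis, BCL2 family, DNA replication, mitosis, histones, NF-kB, interferon, immediate early, glycolysis, oxidative phosphorylation, mitochondrial and ribosomal genes, epithelial, mesenchymal and identity markers, drug targets, and leukocyte, endothelial, fibroblast and erythroid markers. Of them, 1 list, counted in the totals, and 7 single genes are not reported here. Each list of at least 3 measured genes has a median log2 ratio with a 95% interval from order statistics, which for fewer than 6 genes is the range. Its percentile was taken among 10000 random lists of the same size from expressed protein-coding genes, matched in 10 bins of mean expression, as a description of these libraries. A list stood apart below the 2.5 or above the 97.5 percentile. Named genes were the 12 highest and 12 lowest protein-coding genes with at least 5 FPKM in a library, up to 4 members per list with the largest log2 ratio in size and 2 with the highest mean, 16 genes fixed by name, and the 5 most abundant genes of each library.

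Alternatives fixed beforehand were pseudocounts of 0.1 and 5 FPKM, no filter or a mean of at least 5 FPKM, 3 other scalings, protein-coding genes alone, limits of 1.5-fold and 4-fold, and random lists matched also on length. Added after a GC trend and low counts of some genes had been seen were random lists matched also on GC content in 3 bins, removal of a smooth trend (lowess, fraction 0.3) on GC content and then length, leaving out genes with at least 0.2 of their exon bases shared with another gene on the same strand, and a minimum of 20 counts. GC content and length were known for all 10654 genes of the trend. Protein-coding genes sharing 50% or more of their exon bases on the same strand had a median of 0.128 FPKM, against 4.03 for those sharing them on the opposite strand and 4.88 for those sharing none, as counting by strand would give, so values of genes overlapping on the same strand, CCPG1 and MT-ATP8 among them, are uncertain. Families with near-identical copies or many pseudogenes (histones, metallothioneins, HSPA1A, keratins, actins, ferritins and ribosomal proteins) are uncertain too. Genes on the Y chromosome and XIST were left out of the tables of single genes.

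The procedure was tested on simulated data for this comparison, with 200 genes changed among 13039 expressed ones and Poisson counting error alone. A change of 4-fold passed the limit in 100% of 50 genes upwards and 95.9% of 49 downwards, and one of 2-fold, which lies at the limit, in 18.0% of 50 and 22.9% of 48. Unchanged genes passed it in 0.280%. Counting intervals held the true ratio for 95.7% of genes. On the real log2 ratios, 400 random lists of 20 genes were each set against 200 other random lists. Of them, 4.5% stood apart with no shift, a rate set by the way they were drawn, and 82.5% with a log2 shift of 0.5. Lists of genes that vary together were not covered by this. A GC trend laid over the simulated ratios gave a correlation of -0.93, which was 0.0022 after its removal. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.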

Results

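RNA sequencing was analysed from SKOV3 cells, a human ovarian cancer cell line, with or without thioridazine, a phenothiazine antipsychotic that blocks dopamine receptors. The treated cells had received 15 µM for 24 h, and the control cells are described as having no treatment. Each group held 1 library, of 11641110 counts in the control and 9364269 counts in the thioridazine library. The difference between them therefore has no replicate check and no p-value. Intervals given with folds cover counting error only, and a fold compares these 2 libraries, not the conditions. Where the interval of a fold includes 1, no difference was detectable at this depth. The series title speaks of autophagy and of pyrolysis, and the list of pyroptosis genes was taken as the nearest cell death process.

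After thioridazine, transcripts of the endoplasmic reticulum (ER) stress response, sterol synthesis, lysosomes and part of the interferon response were higher, and those of histones, DNA replication and mitosis were lower. DDIT3, which encodes the stress transcription factor CHOP, was 19.0-fold higher (95% counting interval 13.8 to 27.0), from 2.56 to 48.8 FPKM. The ER chaperone HSPA5 (BiP) was 8.50-fold higher (8.29 to 8.70), from 167 to 1415 FPKM, and the stress-induced cytokine GDF15 was 15.4-fold higher (12.3 to 19.5). The collagenase MMP1 had 0 counts in the control and 211 in the thioridazine library, which is at least 70.5-fold higher by the lower 95% counting limit, or 87.4-fold against a floor of 3 counts in the control library. The other genes among the 12 highest were IFIT2, INHBE, MFSD2A, OASL, NOV, RSAD2, IFIT3 and SPINK1. Of these, RSAD2 had 1 control count against 304, a ratio of 378 with an interval of 67.3 to 14975. MFSD2A, a lysophospholipid transporter, was 28.4-fold higher (17.5 to 49.2), and the inhibin subunit gene INHBE was 13.2-fold higher (10.1 to 17.5). The protease inhibitor SPINK1 was 20.8-fold higher (10.3 to 49.2) and NOV, a matricellular protein gene, was 11.2-fold higher (8.55 to 15.0).

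All 12 lowest protein-coding genes were replication-dependent histone genes, with the lowest log2 ratio, on the scale with a pseudocount, for HIST1H2AB, which was 18.9-fold lower (14.9 to 24.3), from 359 to 19.0 FPKM. The lowest genes outside that family, chosen after their values were seen and ordered on the same scale, began with OLR1, a receptor for oxidised lipoprotein, at 15.9-fold (13.0 to 19.6) lower, and MAMDC2 at 14.1-fold (11.2 to 18.2) lower. By plain folds HIST2H3C, at 19.5-fold (14.2 to 27.5) lower, lay below HIST1H2AB, and MEOX1 and EDN2, at 17.3-fold (8.95 to 38.5) and 16.6-fold (7.42 to 46.2) lower, lay below OLR1. The lowest genes outside the family also held the alkaline phosphatase ALPP at 7.92-fold (7.39 to 8.50) lower, IGFBP3 at 6.97-fold (6.58 to 7.40) lower, and cytoplasmic actin ACTG1 at 6.27-fold (6.13 to 6.41) lower. Beta-actin (ACTB), the most abundant gene of the control library, was 4.58-fold lower (4.51 to 4.65), from 2512 to 549 FPKM. In the thioridazine library the most abundant gene was FTH1, the ferritin heavy chain, from 1699 to 4044 FPKM. On GRCh38, DDIT3 (ENSG00000175197) lies on chromosome 12, 57516588 to 57521737, HSPA5 (ENSG00000044574) on chromosome 9, 125234853 to 125241330, MMP1 (ENSG00000196611) on chromosome 11, 102789920 to 102798160 and HIST1H2AB (ENSG00000278463) on chromosome 6, 26033176 to 26033568.

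Among 13042 expressed genes, 1133 were at least 2-fold higher and 807 at least 2-fold lower, so that 58.4% of the genes past the limit were higher. The limit applies to the log2 ratio with a pseudocount of 1 FPKM, so that a low gene such as SMPDL3A can differ by more than 2-fold in plain FPKM without passing it. With both libraries scaled to the same sum over nuclear protein-coding genes, which moves a log2 ratio by up to 0.18, the numbers were 1586 and 606, or 72.4% higher. With median-centring they were 988 and 922, or 51.7% higher, and with the same upper quartile 1056 and 854, or 55.3% higher, so the balance of directions depends on the scaling. The number past the limit depended on the pseudocount, with 1707 higher at 0.1 FPKM and 376 higher at 5 FPKM. Of 30 gene lists with a median, 10 lay above and 5 below 95% of random lists matched on expression. If the lists were random draws of genes, 1.5 would be expected in both directions together. Genes of a list can vary together and some lists share genes, so that value is no test of the number found.

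**Figure D1:**
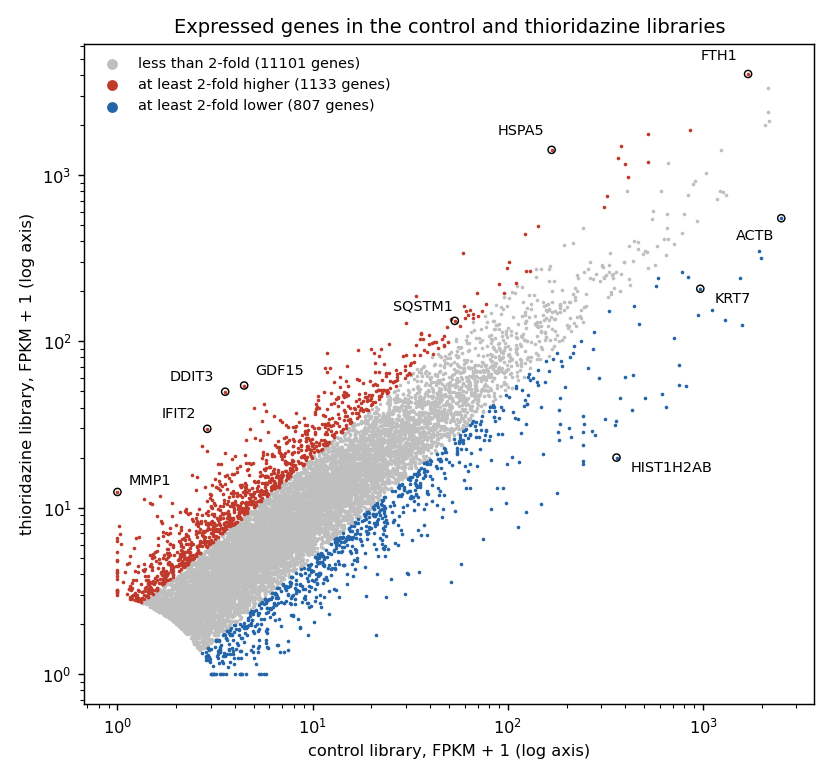
Each point is 1 expressed gene, with its FPKM plus 1 in the control library on the horizontal log axis and in the thioridazine library on the vertical log axis. Red points are the 1133 genes at least 2-fold higher and blue points the 807 at least 2-fold lower on the scale with a pseudocount of 1 FPKM; HSPA5 and FTH1 stand above the bulk of abundant genes and histone, keratin and actin genes below it.

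Genes of protein folding and degradation in the ER were higher together. Of 18 measured members, 15 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 1.47 (95% interval 1.10 to 2.01), at percentile 100 of random lists. The co-chaperones DNAJB9 and DNAJC3 were 7.91-fold higher (6.28 to 10.1) and 5.96-fold higher (5.50 to 6.48), and HERPUD1, which acts in ER-associated degradation, was 5.47-fold higher (5.10 to 5.88). Calreticulin (CALR) was among the most abundant members and was 2.08-fold higher (2.03 to 2.14), from 308 to 642 FPKM, at a log2 ratio of 1.057 that median-centring took below the limit, to 0.996. Of 32 measured targets of the transcription factor ATF4, 16 were higher and 1 was lower past the limit, with a median of 1.03 (95% interval 0.64 to 1.58) at percentile 100. Beyond DDIT3 and GDF15, the phosphatase subunit PPP1R15A, which reverses eIF2α phosphorylation, was 6.44-fold higher (5.77 to 7.21), and the tryptophanyl-tRNA synthetase WARS was 4.73-fold higher (4.46 to 5.02). The amino acid transporter SLC7A5, the list's most abundant member, went the other way at 1.85-fold (1.82 to 1.88) lower, from 706 to 382 FPKM, and DDIT4 was 1.20-fold higher (1.14 to 1.26). The member below the limit was JDP2, a transcription factor of the AP-1 family, at a log2 ratio of -1.21, named after its value was seen.

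Enzymes of cholesterol synthesis were also higher, with 9 of 20 measured genes at least 2-fold higher, 0 lower, and a median log2 ratio of 0.76 (95% interval 0.51 to 1.39) at percentile 99.98. IDI1 was 4.87-fold higher (4.30 to 5.53), squalene epoxidase (SQLE) 4.65-fold higher (4.22 to 5.13), MSMO1 4.11-fold higher (3.63 to 4.68) and HMGCS1 3.60-fold higher (3.30 to 3.94). FDPS, among the most abundant of these enzymes, was 1.38-fold higher (1.32 to 1.45). Of 15 other targets of the sterol-responsive SREBP factors, 6 were higher and 0 lower, with a median of 0.92 (95% interval 0.38 to 1.83) at percentile 99.98. INSIG1 was 6.003-fold higher (5.44 to 6.64), STARD4 4.53-fold higher (3.83 to 5.38), the desaturase SCD 3.64-fold higher (3.54 to 3.73) and fatty acid synthase (FASN) 1.90-fold higher (1.85 to 1.94). Among 4 measured targets of the oxysterol receptor LXR, none passed the limit in either direction, and the median of -0.000644 (95% interval -0.30 to 0.92) lay at percentile 36.3. The listed targets ABCA1 and ABCG1 had a mean below 1 FPKM and were not measured, so the list says little about LXR activity. Of the measured targets, NR1H3 was 1.07-fold higher (0.905 to 1.26), MYLIP 1.45-fold lower (0.910 to 2.34), LPCAT3 1.07-fold lower (0.938 to 1.21) and SMPDL3A 3.64-fold higher (1.94 to 7.23). The LXR median lies so close to 0 that its sign turned under 4 of the alternatives. With the GC and length trend removed the log2 ratio of LPCAT3 turned, from -0.084 to 0.009, and FASN passed the limit, from 0.916 to 1.194.

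Lysosomal genes were also higher, with 7 of 34 at least 2-fold higher, 0 lower and a median log2 ratio of 0.66 (95% interval 0.48 to 0.83) at percentile 100. The sialidase NEU1 was 4.08-fold higher (3.62 to 4.60), the protease cathepsin L (CTSL) 2.89-fold higher (2.65 to 3.15), the proton pump subunit ATP6V1D 2.89-fold higher (2.60 to 3.21) and the membrane protein CD63 2.78-fold higher (2.66 to 2.90). PSAP, the sphingolipid activator precursor, was 1.99-fold higher (1.94 to 2.04). Of 13 autophagy receptors, 4 were higher and 0 lower, with a median of 0.75 (95% interval 0.37 to 1.35) at percentile 99.8. SQSTM1 (p62) was 2.51-fold higher (2.42 to 2.60), from 52.5 to 132 FPKM, and the mitophagy receptor BNIP3L was 2.73-fold higher (2.503 to 2.97). The ER-phagy receptors SEC62 and CCPG1 were 2.76-fold higher (2.52 to 3.02) and 5.77-fold higher (4.48 to 7.51), and NBR1 was 1.34-fold higher (1.27 to 1.41). The value of CCPG1 is uncertain because it overlaps another gene on the same strand. Of 28 genes of the core autophagy machinery, 5 were higher and 0 lower, and the median of 0.29 (95% interval 0.05 to 0.65) lay at percentile 93.4, inside the range of random lists. WIPI1 was 7.82-fold higher (6.70 to 9.17), MAP1LC3B, which encodes LC3, 4.12-fold higher (3.81 to 4.45), ATG4A 3.25-fold higher (2.72 to 3.89) and RB1CC1 2.99-fold higher (2.77 to 3.22). ATG5 was 1.49-fold higher (1.25 to 1.77), BECN1 1.20-fold higher (1.09 to 1.32) and ULK1 1.23-fold higher (1.15 to 1.31), while ATG7 was 1.58-fold lower (1.36 to 1.85) and GABARAPL1 1.74-fold lower (1.603 to 1.89). The machinery median was 0.15 once a trend with GC content and gene length had been removed. With both libraries scaled to the same sum it was 0.45. Removal of the trend ended the calls of SEC62, BNIP3L and RB1CC1, with log2 ratios going from 1.349 to 0.818, 1.390 to 0.977 and 1.497 to 0.994, put PSAP past the limit, from 0.988 to 1.148, and took ATG5 from 0.471 to 0.021 and BECN1 from 0.245 to 0.130.

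Genes of pyroptosis, a lytic cell death through gasdermin pores, differed in both directions. Of 13 measured members, 3 were higher and 1 was lower past the limit, and the median log2 ratio of 0.46 (95% interval -0.51 to 1.11) lay at percentile 96.6, inside the range of random lists. After removal of the GC and length trend the median was 0.17, and over members with a mean of at least 5 FPKM it was 0.13. The inflammatory caspase CASP4 was 2.75-fold higher (2.44 to 3.10), from 4.75 to 13.0 FPKM, TXNIP 3.56-fold higher (3.26 to 3.89) and GSDMB 5.76-fold higher (3.61 to 9.60), from 0.320 to 1.84 FPKM. The pore-forming genes GSDMD and GSDME were 1.67-fold lower (1.36 to 2.07) and 1.16-fold lower (1.05 to 1.27), and the cytokine IL18 was 2.81-fold lower (2.47 to 3.21), from 34.5 to 12.3 FPKM. CASP1 had 14 and 17 counts, below 1 FPKM in both libraries, with a ratio of 1.51 (0.700 to 3.31). IL1B had 0 counts in the control and 6 after thioridazine, at least 1.46-fold higher by the lower counting limit, or 2.49-fold against the same floor. NLRP3 and PYCARD had no row in the tables used here, which list only genes with at least 1 count. With the GC and length trend removed CASP4 was no longer past the limit, from a log2 ratio of 1.289 to 0.816, and CASP1 turned in direction, from 0.170 to -0.136. The pyroptosis median was 0.25 with a pseudocount of 5 FPKM and 0.23 without the filter.

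Interferon-stimulated genes split into a group that was higher and a group that was not. Of 13 measured members, 8 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.97 (95% interval 0.20 to 2.90) at percentile 100. The antiviral genes IFIT2 and IFIT3 were 15.3-fold higher (12.3 to 19.2) and 8.87-fold higher (7.43 to 10.6), OASL was 9.75-fold higher (8.27 to 11.5), and the ubiquitin-like modifier ISG15 was 5.74-fold higher (5.12 to 6.45), from 32.7 to 188 FPKM. OAS3 and IFI6, named after their values were seen, had log2 ratios of -0.86 and -0.02. Without the filter on low values the median over all 20 listed genes was 0.43. With a pseudocount of 5 FPKM it was 1.06. Of 14 immediate early genes, which respond within minutes to growth and stress signals, 9 were higher and 1 was lower, with a median of 1.07 (95% interval 0.26 to 1.88) at percentile 100. EGR1 was 10.4-fold higher (7.75 to 14.1), FOSB 8.08-fold higher (5.91 to 11.3), DUSP5 4.42-fold higher (3.58 to 5.51), KLF6 3.45-fold higher (3.13 to 3.796) and IER3 2.06-fold higher (1.93 to 2.20), which median-centring took below the limit, from a log2 ratio of 1.036 to 0.97, while MYC was the member past the limit in the other direction, at 2.67-fold (2.54 to 2.81) lower. Of 14 genes of NF-kB signalling and inflammatory cytokines, 3 were higher and 1 was lower, with a median of 0.24 (95% interval -0.68 to 1.57) at percentile 76.9. PTGS2 (cyclooxygenase) was 10.4-fold higher (7.55 to 14.7), CXCL8 4.04-fold higher (2.91 to 5.71) and LIF 4.24-fold higher (3.68 to 4.90), whereas RELB was 2.67-fold lower (2.16 to 3.34), NFKBIA 1.65-fold lower (1.502 to 1.82) and NFKB2 1.46-fold lower (1.34 to 1.58). That median changed sign to -0.41 over members with a mean of at least 5 FPKM and to -0.12 without the filter. It was 0.07 with a pseudocount of 5 FPKM, 0.37 with the same sum and 0.06 after removal of the trend, where RELB was no longer past the limit, from a log2 ratio of -1.222 to -0.879.

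Genes of cell proliferation were lower together. Of 26 DNA replication genes, 19 were at least 2-fold lower and 0 higher, with a median log2 ratio of -1.31 (95% interval -1.58 to -1.01) at percentile 0. The replication factors GINS2, MCM10 and CDC45 were 4.63-fold lower (3.95 to 5.45), 5.92-fold lower (4.72 to 7.52) and 4.62-fold lower (3.82 to 5.62), and the ribonucleotide reductase subunit RRM2 was 4.31-fold lower (3.76 to 4.95). The sliding clamp PCNA was 2.70-fold lower (2.47 to 2.95) and RRM1 2.03-fold lower (1.94 to 2.13). Of 27 mitosis genes, 19 were lower and 0 higher, with a median of -1.37 (95% interval -1.60 to -0.78) at percentile 0. The mitotic kinases PLK1 and CDK1 were 5.12-fold lower (4.63 to 5.67) and 3.83-fold lower (3.34 to 4.40), cyclin A (CCNA2) was 3.95-fold lower (3.55 to 4.41), UBE2C 3.49-fold lower (3.09 to 3.96), TPX2 2.26-fold lower (2.14 to 2.38) and CDC20 3.00-fold lower (2.77 to 3.25). All 18 measured replication-dependent histone genes were at least 2-fold lower, with a median of -3.25 (95% interval -3.66 to -2.85) at percentile 0. The linker histone gene HIST1H1B was 16.5-fold lower (14.5 to 18.8), HIST1H3G 15.7-fold lower (13.9 to 17.9), HIST1H2BB 14.6-fold lower (10.1 to 21.9), HIST1H3B 12.7-fold lower (11.6 to 13.96) and HIST2H2AC 6.44-fold lower (6.005 to 6.92). The 67 histone genes of these clusters took 1.37% (1.37 to 1.38) of control counts and 0.181% (0.179 to 0.184) of thioridazine counts, with exact binomial intervals. Histone genes have near-identical copies, so the level of a single copy is uncertain.

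**Figure D2:**
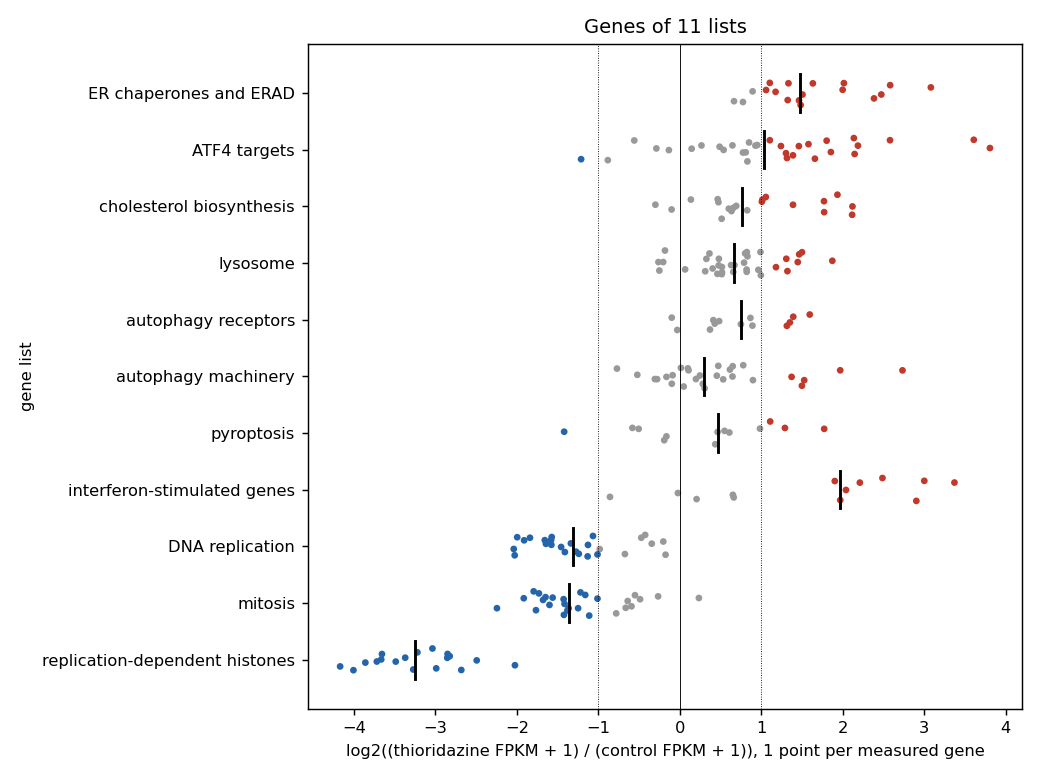
Each point is 1 measured gene of the list named on the vertical axis, placed by its log2 ratio of thioridazine to control FPKM with a pseudocount of 1 on the horizontal axis; black bars are list medians, and dotted lines mark the 2-fold limits. All 18 histone genes lie below the lower limit, 15 of 18 ER genes above the upper one, and autophagy machinery and pyroptosis genes on both sides of 0.

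Of 8 targets of the transcriptional coactivator YAP, 4 were lower and 0 higher, with a median log2 ratio of -1.32 (95% interval -2.28 to -0.24) at percentile 0. CYR61 was 4.93-fold lower (4.66 to 5.23), CTGF 5.30-fold lower (4.33 to 6.54), AJUBA 4.06-fold lower (3.78 to 4.35) and AMOTL2 3.56-fold lower (3.32 to 3.83), and the receptor kinase AXL was 1.77-fold lower (1.69 to 1.85). Among 7 epithelial markers, 3 were lower and 1 was higher. The keratins KRT7, KRT8 and KRT18 were 4.69-fold lower (4.58 to 4.80), 3.71-fold lower (3.62 to 3.799) and 2.98-fold lower (2.91 to 3.06), and the tight junction gene CLDN3 was 3.11-fold higher (1.82 to 5.51). The epithelial median of -0.52 (95% interval -2.22 to 1.14) lay at percentile 5.46, and it was -0.25 after removal of the GC and length trend. Of 8 mesenchymal markers, 1 was higher and 0 lower, with a median of 0.53 (95% interval -0.39 to 2.10) at percentile 97.2 and of 0.22 after removal of the trend. The transcription factor SNAI2 was 5.53-fold higher (4.47 to 6.90), FN1 (fibronectin) 1.70-fold higher (1.66 to 1.74), ZEB1 2.00-fold higher (1.65 to 2.43) and SNAI1 1.84-fold higher (1.12 to 3.06), while vimentin (VIM) was 1.06-fold higher (1.03 to 1.08) and CDH2 1.32-fold lower (1.26 to 1.39). The 4 measured genes of ovarian carcinoma and SKOV3 identity had a median of -0.86 (95% interval -1.37 to 0.27) at percentile 1.18, or 3.51 among random lists matched also on GC content. Of the 7 genes listed, MUC16, PAX8 and WT1 had a mean below 1 FPKM and were not measured. These ratios compare the libraries and do not test the identity of the cells. The levels of these genes were not compared with reference values for SKOV3 either, so the stated cell line was not checked. ERBB2 was 1.91-fold lower (1.70 to 2.14), from 8.55 to 4.48 FPKM. CDKN2A was 1.94-fold lower (1.79 to 2.11), from 39.4 to 20.3 FPKM, and mesothelin (MSLN) 1.21-fold higher (1.14 to 1.28). Without the filter on low values the epithelial, mesenchymal and identity medians were -0.15, 0.28 and -0.02. Over members with a mean of at least 5 FPKM the epithelial median was -1.73, and the mesenchymal one was 0.80 and 0.20 with pseudocounts of 0.1 and 5 FPKM.

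Of 13 BCL2 family genes, 2 were higher and 1 was lower, with a median log2 ratio of 0.15 (95% interval -0.56 to 0.79) at percentile 69.1. The death-promoting members PMAIP1 (NOXA) and HRK were 3.34-fold higher (2.86 to 3.92) and 4.43-fold higher (3.37 to 5.91), BIK and BID were 3.47-fold lower (1.87 to 6.91) and 2.05-fold lower (1.77 to 2.38), and the protective members MCL1 and BCL2L1 were 1.24-fold higher (1.18 to 1.29) and 1.21-fold lower (1.15 to 1.27). The BCL2 family median was 0.01 without the filter, 0.28 over members with a mean of at least 5 FPKM, 0.09 with median-centring and 0.32 with the same sum.

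Of 11 ferroptosis regulators, 3 were higher and 0 lower, with a median log2 ratio of 0.64 (95% interval -0.21 to 1.58) at percentile 99.3 and of 0.35 after removal of the GC and length trend, at percentile 96.3, inside the range of random lists. The cystine transporter SLC7A11 was 3.66-fold higher (3.23 to 4.16), FTH1 2.38-fold higher (2.35 to 2.41), FTL 1.79-fold higher (1.73 to 1.84) and ACSL4 1.83-fold higher (1.72 to 1.96). Of 14 NRF2 targets, 4 were higher and 0 lower, and the median of 0.37 (95% interval -0.53 to 1.58) at percentile 94.7 became 0.12 after removal of the trend. OSGIN1 was 7.71-fold higher (5.59 to 10.9) and heme oxygenase (HMOX1) 3.56-fold higher (2.89 to 4.41). Of 12 cytosolic and mitochondrial heat shock genes, 1 was higher and 0 lower, with a median of 0.33 (95% interval -0.15 to 0.54) at percentile 95.8. HSPH1 was 2.86-fold higher (2.67 to 3.06) and CHORDC1 1.92-fold higher (1.77 to 2.09), while HSPB1 and the mitochondrial chaperone HSPD1 were 1.86-fold lower (1.76 to 1.96) and 1.69-fold lower (1.64 to 1.75). None of 5 genes of the metallothionein list passed the limit, and their median was 0.31 (95% interval -0.40 to 0.85) at percentile 82.8. MT2A was 1.81-fold higher (1.70 to 1.93), MT1E 1.24-fold higher (1.12 to 1.38), SLC30A1 1.39-fold higher (1.27 to 1.51) and MT1F 1.52-fold lower (0.946 to 2.5001). The NRF2 median was 0.25 with a pseudocount of 5 FPKM, 0.18 without the filter and 0.18 over members with a mean of at least 5 FPKM. With the same sum the heat shock and metallothionein medians were 0.50 and 0.485. With the trend removed SLC30A1 turned in direction, from a log2 ratio of 0.449 to -0.027.

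Messenger RNAs encoded by the mitochondrial genome took 1.03% (1.02 to 1.04) of control counts and 1.76% (1.75 to 1.76) of thioridazine counts. Of 13 such genes, 8 were higher and 1 was lower, with a median log2 ratio of 1.22 (95% interval 0.16 to 1.75) at percentile 100. The complex I subunits MT-ND5, MT-ND4L and MT-ND1 were 3.94-fold higher (3.84 to 4.04), 3.50-fold higher (3.15 to 3.89) and 3.37-fold higher (3.27 to 3.47). The complex IV subunits MT-CO2, MT-CO3 and MT-CO1 were 1.54-fold higher (1.51 to 1.57), 1.11-fold higher (1.09 to 1.14) and 1.03-fold lower (1.01 to 1.04). The gene past the lower limit, MT-ATP8, is uncertain because it overlaps another gene on the same strand. It had 5 counts in the control and 0 after thioridazine, a difference not detectable at such counts, with a lower counting limit of 0.737-fold lower. With MT-ATP8 at a floor of 3 counts the median was 1.22. Of 30 nuclear genes of oxidative phosphorylation, 0 were higher and 1 was lower, and their median of -0.30 (95% interval -0.41 to 0.02) lay at percentile 5.07, or 0.530 among lists matched also on GC content. SDHA was 2.25-fold lower (2.14 to 2.37), ATP5F1B 1.95-fold lower (1.88 to 2.01), NDUFV1 1.94-fold lower (1.80 to 2.09) and COX5B 1.12-fold lower (1.04 to 1.20). Of 40 cytosolic ribosomal protein genes, 0 were higher and 1 was lower, with a median of -0.35 (95% interval -0.46 to -0.17) at percentile 11.99. RPS15 was 2.38-fold lower (2.26 to 2.51), RPLP0 1.74-fold lower (1.72 to 1.77), RPS19 1.68-fold lower (1.62 to 1.74), RPS2 1.59-fold lower (1.56 to 1.62) and RPL7A 1.64-fold lower (1.61 to 1.68), while RPS27 was 1.93-fold higher (1.80 to 2.07). With both libraries scaled to the same sum, the oxidative phosphorylation and ribosomal medians were -0.13 and -0.17. Of 22 genes of glycolysis and hypoxia, 3 were higher and 1 was lower, with a median of -0.12 (95% interval -0.78 to 0.81) at percentile 28.6, which changed sign to 0.05 under that scaling. HK2 was 3.65-fold higher (3.38 to 3.95), P4HA1 2.46-fold higher (2.23 to 2.73) and VEGFA 2.36-fold higher (2.16 to 2.60), whereas ANKRD37, ENO1 and GAPDH were 2.36-fold lower (1.87 to 2.99), 1.96-fold lower (1.92 to 2.00) and 1.72-fold lower (1.69 to 1.75). The glycolysis and hypoxia median was -0.07 with a pseudocount of 5 FPKM, -0.27 over members with a mean of at least 5 FPKM, -0.18 with median-centring and -0.05 after removal of the GC and length trend, where P4HA1 was no longer past the limit, from a log2 ratio of 1.249 to 0.944.

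Of 15 receptor and channel genes through which thioridazine is known to act, 10 had a row and 4 were measured at a mean of at least 1 FPKM. Of these, 1 was lower and 0 higher, with a median log2 ratio of -0.29 (95% interval -1.03 to 0.29) at percentile 22.9. The calmodulin genes CALM2 and CALM3 were 2.07-fold lower (1.98 to 2.16) and 1.56-fold lower (1.44 to 1.70), and the histamine receptor HRH1 was 1.31-fold higher (1.05 to 1.63). Of the dopamine receptor genes, DRD1, with 0 and 2 counts, and DRD4, with 8 and 11, lay below 1 FPKM, and DRD2, DRD3 and DRD5 had no row. Markers of other cell types stayed low, with no measured gene among 6 leukocyte, 4 endothelial and 4 erythroid markers. Of 6 fibroblast markers 1 was measured, the collagen gene COL1A1, at 7.17 to 10.0 FPKM, 1.40-fold higher (1.27 to 1.54). The median of the receptor and channel list was -0.04 without the filter, -0.625 over members with a mean of at least 5 FPKM and -0.12 with the same sum.

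**Figure D3:**
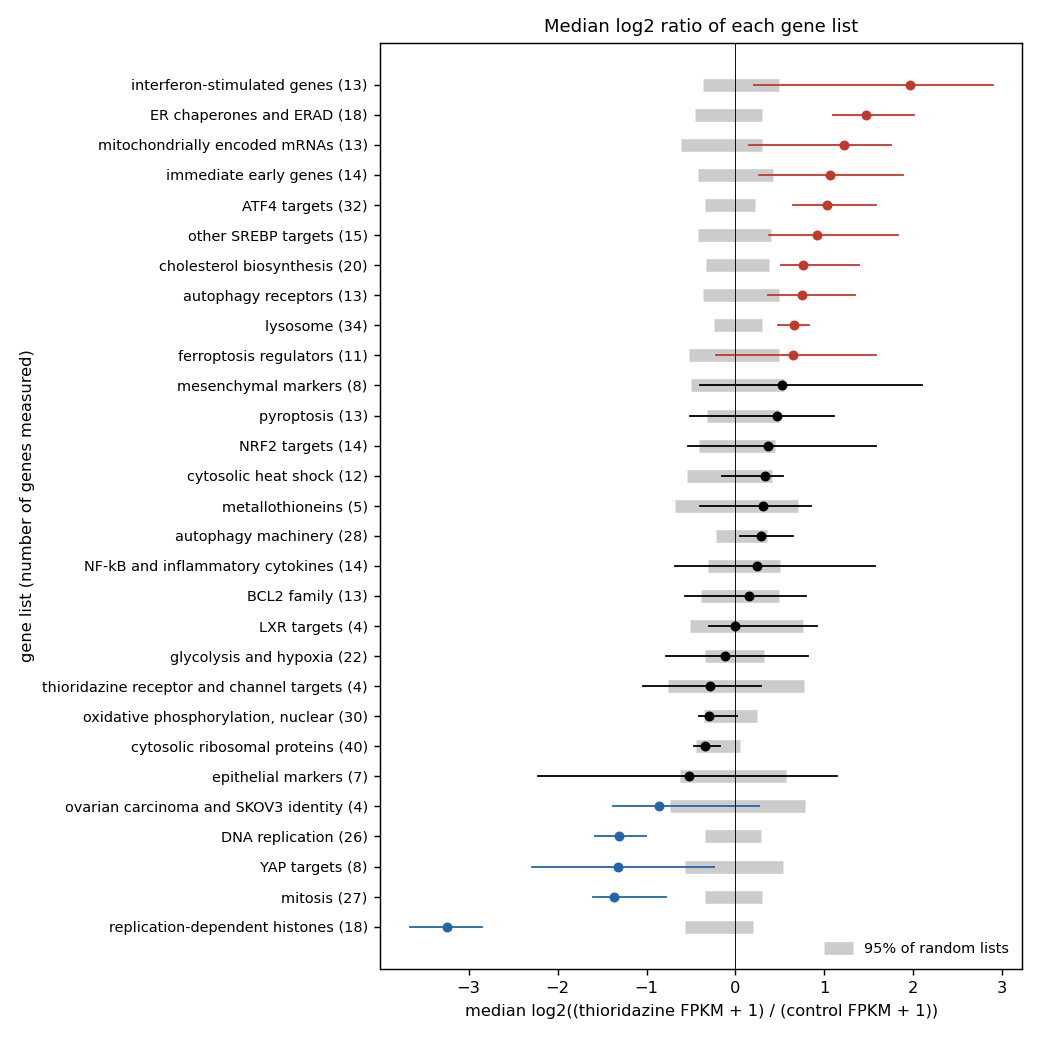
Each row is 1 gene list with its number of measured genes, and the horizontal axis is the median log2 ratio of thioridazine to control FPKM with a pseudocount of 1; points are medians, thin lines their 95% intervals from order statistics, and grey bars the middle 95% of 10000 random lists matched on expression. The 10 red lists lie above and the 5 blue lists below 95% of their random lists, from the interferon list at 1.97 to the histone list at -3.25.

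Across 10654 expressed protein-coding genes, the log2 ratio was lower at higher GC content, with a Spearman correlation across genes of -0.38, where genes are not independent replicates. The median was 0.53 (95% interval 0.49 to 0.57) in the 10% of genes with the lowest GC content and -0.27 (-0.32 to -0.22) in the 10% with the highest. The correlation with gene length was 0.14. With the trend on both removed, 887 genes were at least 2-fold higher and 787 at least 2-fold lower. Among random lists matched also on GC content, 11 of the 30 lists lay above and 5 below the middle 95%.

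**Figure D4:**
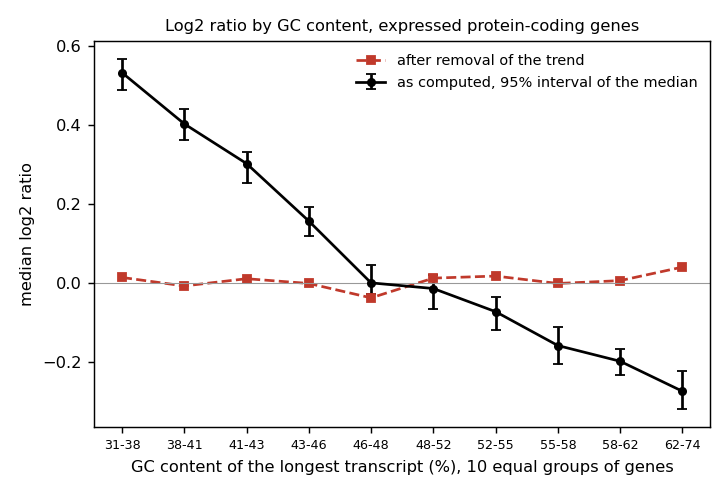
Black points are the median log2 ratio of thioridazine to control FPKM, with 95% intervals from order statistics, in 10 groups of about equal size ordered by the GC content of the longest transcript on the horizontal axis; red squares are the same medians after removal of the trend. The medians run from 0.53 in the lowest to -0.27 in the highest group.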

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

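The GC and length settings, the setting without overlapping genes and the one with at least 20 counts were chosen after seeing the data. The number of genes at least 2-fold higher moved from 1133 to 1707 with a pseudocount of 0.1 FPKM, 376 with one of 5 FPKM and 705 over genes with a mean of at least 5 FPKM. The number at least 2-fold lower moved from 807 to 335 with a pseudocount of 5 FPKM. Limits of 1.5-fold and 4-fold gave 2751 and 99 higher and 2091 and 117 lower genes, by their construction. Under all other settings both numbers stayed within 1.5 times. Of the medians of the 30 lists, that of the lysosome list left its 95% interval with a pseudocount of 5 FPKM, at 0.46. All other medians stayed inside their intervals, which are wide for short lists, and the LXR list had no value at a mean of at least 5 FPKM, with fewer than 3 genes left. Matched also on GC content, the percentile of oxidative phosphorylation moved from 5.07 to 0.53 and that of the identity genes from 1.18 to 3.51, and that of the list left out of the report from 97.0 to 98.4, as it did matched on length; the cause was not tested. The other lists stayed on their side of the limits under both matchings. With the trend removed, the ferroptosis and identity lists came to lie inside the limits, at percentiles 96.3 and 3.14, and oxidative phosphorylation and the list left out passed them, at 0.75 and 99.9. Of 208 genes named by the rule or picked afterwards, 140 were at least 2-fold higher or lower, and 140, 138 and 130 of them stayed so in the same direction with a pseudocount of 0.1, with median-centring and with the GC and length trend removed. Of all 208, 27, 36 and 105 left their counting interval under these settings, and 0, 1 and 6 took the other sign. ATP5F1B and ENO1 passed the limit with median-centring only, and BID, IL1B and SMPDL3A with a pseudocount of 0.1 only. No alternative gives a replicate, and depth limits genes such as IL1B and CASP1, whose counts are few. The counts of MT-ATP8 are few as well, but it overlaps another gene on the same strand, so depth need not be the reason.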

Other observations

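The tests by scaling, other cultures, short transcripts, poly(A) tails and S phase, and the GC-matched percentile of the interferon list, were chosen after the result was seen, as were the genes of this paragraph. MALAT1, a nuclear long noncoding RNA, was 3.45-fold higher (95% counting interval 3.41 to 3.49), from 366 to 1264 FPKM, and NEAT1, a scaffold of paraspeckles, was 2.20-fold higher (2.13 to 2.27). UCA1, a long noncoding RNA first described in bladder cancer, was 4.70-fold higher (4.28 to 5.16). KRT7-AS, antisense to KRT7, was 5.42-fold lower (4.80 to 6.14), beside KRT7 at 4.69-fold (4.58 to 4.80) lower. KRT7 shares 0.077 of its exon bases with the opposite strand, and whether the counts of this pair are separate was not tested. FOLR1, the folate receptor targeted in ovarian cancer, was 2.31-fold higher (2.25 to 2.36), from 521 to 1202 FPKM. Among histone genes outside the replication-dependent clusters, H1F0 and H3F3B were 1.05-fold higher (1.01 to 1.10) and 1.09-fold higher (1.04 to 1.14). In contrast, H2AFZ was 1.43-fold lower (1.36 to 1.51), H3F3A 1.77-fold lower (1.65 to 1.90), H1FX 2.17-fold lower (2.06 to 2.28) and H2AFX 4.30-fold lower (3.86 to 4.79). With the GC and length trend removed NEAT1 and H1FX were no longer past the limit, with log2 ratios from 1.102 to 0.860 and -1.111 to -0.724. H3F3A passed it under that setting, from -0.808 to -1.130.

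ER chaperone and ATF4 target genes together had a median log2 ratio of 1.31 (95% interval 0.926 to 1.504) over 50 genes. A trend with GC content and length as the whole source is argued against by the median of 1.164 (1.004 to 1.505) after its removal. A single factor acting on all FPKM values is argued against by the median of all expressed protein-coding genes, 0.061 (0.045 to 0.076). FPKM is already scaled to the total of each library, so this median cannot show a difference in the amount of RNA per cell. The lists were higher relative to the bulk of genes. A difference between the 2 cultures other than the drug cannot be told apart from thioridazine, because there was 1 library per group. An ER stress response to thioridazine is a hypothesis that remains open with it.

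Replication-dependent histone genes had a median log2 ratio of -3.25, and -3.138 (-3.65 to -2.85) after removal of the GC and length trend, which argues against that trend. For poor recovery of short transcripts, 1300 other genes of 312 to 2411 bases had a median of -0.086 (-0.14 to -0.06). This argues against a loss across that whole range. Histone genes such as HIST1H4J, HIST2H2AC and HIST2H3D, of 373, 390 and 411 bases, lie near its short end. The test was not matched to those lengths, so a loss limited to the shortest transcripts stays open. A smaller share of cells in S phase may contribute, as the DNA replication list lay at percentile 0 of random lists. That list's median of -1.306 (-1.58 to -1.01) is smaller in size than that of the histones. How far a smaller S phase share would lower each list was not measured, so the gap need not have a further source. Poor recovery of RNA without a poly(A) tail stays open, as the test could not decide it. That test could argue against it only with a DNA replication median below the whole interval of the histone median. However, ribosomal RNA depletion, used here, does not select on such tails, and MALAT1, whose mature end has none, was higher. A difference between the cultures remains open here too.

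Interferon-stimulated genes had a median log2 ratio of 1.97 (0.20 to 2.90). The test set beforehand, removal of the GC and length trend, left 1.695 (0.10 to 2.79), an interval too wide to decide, while the list lay at percentile 100 of random lists matched on GC content, which argues against GC content as the whole source. A broad interferon response was tested, as set beforehand, on 21 measured genes of 28 further interferon-inducible ones, of which 3 were at least 2-fold higher (SAMD9, HERC5 and DDX60) and 0 lower. Removal of the trend took SAMD9 below the limit, from a log2 ratio of 1.246 to 0.709, while HERC5 and DDX60 stayed past it. The median of the 21 genes, 0.169 (-0.37 to 0.62) at percentile 78.2, missed the limits chosen beforehand for this test. Its interval overlaps that of the list, so the question stays open. A response limited to part of the interferon programme may be a hypothesis for further libraries.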
